A study of Lens culinaris subsp. culinaris with 10 samples.

How the data were processed

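Gene expression was measured on 2-colour cDNA arrays in the lentil (Lens culinaris subsp. culinaris) accessions ILL7537 and ILL6002. Plants 14 days old were sprayed with about 5 mL of a spore suspension (1e+06 spores per mL) of Ascochyta lentis, the fungus that causes Ascochyta blight, or with water as a mock. Leaf and stem of 5 plants were pooled, and RNA was taken 6, 24, 48, 72 and 96 h later. Each of the 10 genotype-by-time groups has 3 slides, described in the labels only as biological replicates. Each slide carries the inoculated and the mock RNA of its group, 1 in Cy5 and 1 in Cy3, and 6 complete grids, which are technical replicates. The slide is the unit of replication here, so the number of slides limits the precision of every value.

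The deposited channel files, 60 in all, hold spot intensity as quantified by the authors with ImaGene: signal and background means and medians for 1 channel of 1 slide, with no background subtracted. Other columns deposited by the authors beside the intensity values, namely spot positions and quality marks, were used to match the channels and to leave spots out. The authors also deposited a table of log2 ratios, 1 value per feature and group. Per the file headers, these log2 values were made in GeneSight by local background subtraction, omission of marked or dim spots, LOWESS over the slide, the inoculated over mock ratio, and the mean over the spots of 3 slides. The deposited log2 table was only set beside the recomputed ratios. Its columns had medians of 0.01 (ILL7537 6 h), 0.05 (24 h), 0.08 (48 h), 0.01 (72 h) and -0.0056 (96 h), and of -0.0067, -0.0056, 0.05, 0.02 and -0.01 at the same times in ILL6002. Which spots entered each deposited mean, and by how much the log was shifted, is not known.

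The dye of each channel was taken from the scan name at the end of its file, and otherwise from the file name. On 3 slides (ILL7537 24 h replicate 2, ILL7537 72 h replicate 3 and ILL6002 72 h replicate 3) these statements differed. On all 30 slides the channel taken as Cy3 had the higher background. Inoculated RNA was in Cy5 on 18 slides and in Cy3 on 12. The scan names of the 2 channels differed on 1 slide, ILL6002 24 h replicate 2; ILL7537 6 h replicate 1 could not be compared because its inoculated channel file carries no scan name.

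In R 4.3.3 with limma 3.58.1, signal and background means were background-corrected by the normexp method (offset 50), and spots marked poor or marked by hand were left out. The log2 ratio of inoculated over mock was normalised by loess over the whole slide (span 0.3) and averaged over the grids. Negative controls, blank spots, spots with no ID and the Cy5 spike were left out, leaving 759 features. The 3 features whose IDs carry a NORMCON tag beside a CA number were kept and tested. All 30 slides entered 1 linear model with a coefficient per group and a dye term per feature, and limma's moderated test was applied. A ratio was called when its p, adjusted by Benjamini-Hochberg within the comparison, was under 0.05. Comparisons were the 10 groups, the mean over the 5 times and the change over times (moderated F) in each genotype, and the difference ILL7537 minus ILL6002 at each time and on average. Where a feature lacked a slide value (13 features, 14 values), the model was solved exactly for the slides present. For a named feature of 1 group, a fold is given only where both channels exceeded 2 times background on at least 2 slides and none was saturated; this was settled after the values were seen. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

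The procedure was tested on simulated slides with the layout and background of these, to which changes were added. The simulated noise was independent between slides and equal in spread on each, whereas the SD of real slide ratios ran from 0.371 to 1.05. More features were changed than were called in any real group, which eases the adjusted p threshold. The rates below therefore do not carry over to the real slides. It recovered 67 of 100 changes of 2-fold and 100 of 100 changes of 4-fold, and called 5 unchanged features in the changed group and 1 over the 9 unchanged groups.

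Before the data were examined, a rule was fixed for the features to be named. In each genotype it takes the called features with the same sign on all 3 slides and the largest log2 ratio; for the genotype difference it takes the smallest p, passing or not. The feature IDs come with no gene names in the files used here, so at most 2 higher and 2 lower features per comparison are printed, by ID, and the gene lists fixed beforehand (pathogenesis-related proteins, phenylpropanoid enzymes and others) could not be built. For the same reason no statement is made on the kind of gene.

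Another 14 ways of processing were chosen before the data were examined and run: background subtraction with the authors' spot filter, no background correction, loess within grids, median centring, equal slide spread, no spot left out, only features over background, no dye term, each group on its own slides, a block for replicate number, array weights, a 1.83-fold minimum, and the authors' test on slide means or on grid values. Each of the 30 slides was also left out in turn. Another 4 alternatives were chosen after seeing the data. Counts were set against regroupings of the slides, drawn 100 times where more were possible.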

Results

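Inoculated and mock-treated leaf and stem of the lentil accessions ILL7537 and ILL6002 were compared on 30 slides, 3 for each genotype at 6, 24, 48, 72 and 96 h after spraying with Ascochyta lentis. The series concerns resistance to Ascochyta blight; the labels do not state which accession is resistant. Of the 759 features tested, 236 exceeded 2 times background in at least 1 channel on all 30 slides and 71 did so on none. Per slide, 37.8% to 76.1% of spots exceeded 2 times background in Cy5 and 21.7% to 72.4% in Cy3. Slides were dimmer at 24 h (median 46.7% of spots) and 48 h (49.9%) than at 6 h (66.5%), 72 h (61.9%) and 96 h (61.3%); both groups with calls at a single time, ILL7537 48 h and ILL6002 24 h, belong to these dimmer times. Between 0.17% and 22.2% of spots per channel were saturated, which compresses ratios of the brightest features. Negative control spots exceeded 2 times background in at most 5% of cases in Cy5 and blank spots in 8.2%, against 62.3% for the tested features. Ratios below are log2 of inoculated over mock, from 3 slides per group. Their standard error (SE) rests on the spread of a feature pooled over all 30 slides. It therefore does not measure how far the 3 slides of a group differed, and neither does the adjusted p.

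The first question was which features responded to inoculation in ILL7537. At 48 h, 21 features were called, 17 higher and 4 lower in inoculated tissue. CA0011 NORMCON2, whose ID carries a tag for a normalisation control, was higher by 1.73 (SE 0.417, adjusted p = 0.0369), and U459 was higher by 1.47 (SE 0.331, adjusted p = 0.0369). U071 had a ratio of -1.39 (SE 0.375, adjusted p = 0.0436) and LS0193 one of -1.09 (SE 0.262, adjusted p = 0.0369), a 2.13-fold difference. Of the 21 called features, 20 had the same sign on 3 of 3 slides, which the rule for naming required of these 4. The size of the ratios varied between slides, with an SD over the 3 slides of 1.49 for CA0011 NORMCON2 and 1.35 for U459. CA0011 NORMCON2 had 3.37, 1.38 and 0.45, and U459 had 2.86, 1.59 and 0.17. The lowest value of each came from the slide that had inoculated RNA in Cy3. U071 had -0.88, -0.46 and -2.70, the last on that same slide (replicate 3), and its ratio was -0.71, no longer called, without it. CA0011 NORMCON2 was saturated in the inoculated channel on 1 slide and exceeded 2 times background in the mock channel on 2. The mock channel of U459 and the inoculated channel of U071 exceeded it on 1 of the 3 slides, so no fold is given for these 3 features. On replicate 1, which had the largest ratios of CA0011 NORMCON2 and U459, the mock channel had a median background of 6996, the highest of the 30 slides, and 22.0% of its spots exceeded 2 times background; the median SD over its grids was 0.582, the second highest of the 30 slides. The ILL7537 48 h calls rested on particular slides: 0 features were called without replicate 1, 1 without replicate 2 and 64 without replicate 3. Without replicate 3 only slides with inoculated RNA in Cy5 were left, so a dye bias particular to 48 h could not be told from a response. The count of 21 also fell to 0 with median centring, no background correction, equal slide spread or array weights. It was 0 too with each group on its own slides or the dye profile scaled per slide, and 1 without the 3 slides with differing dye statements. With the authors' background and spot filter it was 2, of which 1 was among the 21.

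In ILL7537 at the other times no feature was called by limma, and the numbers at an unadjusted p under 0.05 were 10 at 6 h, 51 at 24 h, 30 at 72 h and 18 at 96 h, where chance gives 38. Averaged over the 5 times, 1 feature was called: CA0705 was higher by 0.75 (SE 0.153, adjusted p = 0.0441). Its ratios were 0.14 at 6 h, 1.02 at 24 h, 1.40 at 48 h, 0.70 at 72 h and 0.47 at 96 h. Leaving out single slides of ILL7537 moved this count between 0 and 51, the latter without ILL7537 48 h replicate 3, and array weights gave 59. The call of CA0705 was lost under 17 of 30 alternatives, among them 11 of the 15 single slides left out (adjusted p up to 0.154), loess within grids, the dye profile scaled per slide, and replicate number or time by replicate number as a block. Without ILL7537 24 h replicate 1 the 1 call was another feature. No feature passed the test for change between times in ILL7537 (smallest adjusted p = 0.73; 16 at an unadjusted p under 0.05).

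In ILL6002 the calls came at 24 h, when 4 features passed, 3 higher and 1 lower. CA0011 NORMCON2 was higher by 2.03 (SE 0.417, adjusted p = 0.0148), with 1.26, 2.46 and 2.36 on the 3 slides; its mock channel exceeded 2 times background on 1 of them, so no fold is given. U016 was higher by 1.16 (SE 0.225, adjusted p = 0.0148), a 2.23-fold difference, with 0.93, 1.65 and 0.90. CA0640 had a ratio of -0.91 (SE 0.187, adjusted p = 0.0148), but neither channel exceeded 2 times background on any of the 3 slides, so no fold is given. All 4 called features had the same sign on 3 of 3 slides, which the rule for naming required of the 3 named. Without ILL6002 24 h replicate 2, whose channels carry different scan names, 0 features were called, against 26 without replicate 1 (all 4 of these features among them) and 10 without replicate 3 (2 of the 4); median centring, each group on its own slides and the dye profile scaled per slide also gave 0. Without replicate 2 the ratios were 1.81 (SE 0.514) for CA0011 NORMCON2, 0.92 (SE 0.263) for U016 and -0.95 (SE 0.228) for CA0640.

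**Figure D1:**
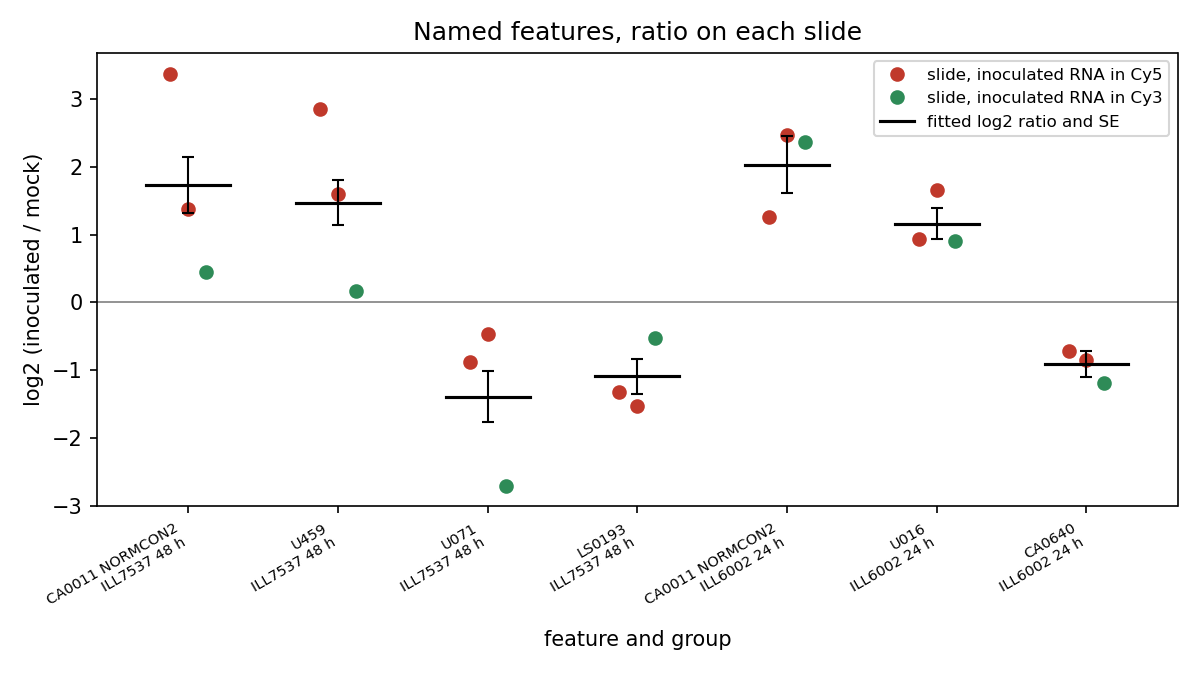
Log2 ratio of inoculated over mock RNA (vertical axis) for the named features of ILL7537 at 48 h and ILL6002 at 24 h (horizontal axis). Points are the 3 slides, coloured by the dye of the inoculated RNA, and bars are the fitted ratio with its SE. CA0011 NORMCON2 lies above 0 on all 3 slides in both groups, as the rule for naming required.

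In ILL6002 no feature was called by limma at 6, 48, 72 or 96 h, with 36, 109, 32 and 30 at an unadjusted p under 0.05; array weights gave 55 at 72 h. The ILL6002 48 h count of 0 became 122 without replicate 2, whose ratios ran against those of the other slides (r over features -0.575 with replicate 1 and -0.651 with replicate 3). Without replicate 2 only slides with inoculated RNA in Cy5 were left in that group. Averaged over the 5 times, 0 features passed in ILL6002 (smallest adjusted p = 0.199; 87 at an unadjusted p under 0.05), though median centring gave 59. For change between times in ILL6002, 0 passed (smallest adjusted p = 0.211; 69 at an unadjusted p under 0.05), and 23 did without ILL6002 48 h replicate 2.

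The accessions were compared by the difference in their response. Such a difference could not by itself be tied to resistance, and the labels do not state which accession is resistant. No feature passed in the difference ILL7537 minus ILL6002 by limma at 6, 24, 48, 72 or 96 h, with 5, 23, 54, 20 and 14 at an unadjusted p under 0.05. Nor did any pass on average over the times (smallest adjusted p = 0.748; 30 at an unadjusted p under 0.05). The smallest adjusted p, 0.123, came at 48 h for U013, with a difference of -1.44 (SE 0.344), and for U256, with -1.19 (SE 0.282). U013 had a ratio of -0.62 in ILL7537 and 0.82 in ILL6002 at 48 h, and U256 had -0.69 and 0.50. At 72 h U258 differed by -1.18 (SE 0.288, adjusted p = 0.315) and U430 by -0.76 (SE 0.215, adjusted p = 0.43). Both passed with array weights, with equal slide spread and without ILL6002 72 h replicate 3. Neither passed under the other 18 alternatives that gave a value. With no background correction they fell to -0.46 and -0.145 (limma adjusted p = 0.997 for each), and with the authors' spot filter they had no value. U256 passed at 48 h without ILL7537 48 h replicate 3, the only one of 22 alternatives to call it. With no background correction U256 fell to -0.48 (limma adjusted p = 0.823). At 24 h the smallest p belonged to CA0640 (0.90) and LS0279 (1.02), and at 96 h to U280 (1.25) and U117 (0.69), each with an adjusted p of 0.981 or more. On average over times, LS1005 (0.48) and U280 (0.56) had the smallest p among positive differences, and U258 (-0.42) and U043 (-0.63) among negative ones. The median SE of a difference at 1 time was 0.373 to 0.378, and array weights gave 8 calls at 72 h.

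Side by side, the accessions' fitted ratios correlated over the 759 features at r = 0.258 at 6 h, 0.533 at 24 h, 0.514 at 48 h, 0.189 at 72 h and 0.039 at 96 h; features are not independent replicates. Between the accessions at different times, r had a median of 0.124 (20 pairs, from -0.203 to 0.475). Between times within an accession it had a median of 0.183 (20 pairs, from -0.175 to 0.535). Of the 21 features called in ILL7537 at 48 h, 20 had the same sign in ILL6002 at 48 h (median ratio 0.41), where 70.5% of all features did. The smallest adjusted p of the 21 in the difference was 0.493. The 48 h slides in Cy5 (ILL7537 replicates 1 and 2, ILL6002 replicates 1 and 3) had a mean r of 0.623 between accessions. ILL6002 replicate 2, in Cy3, had a mean r of -0.573 with those of ILL7537. After subtraction of dye profiles the Cy5 slides had 0.5 between accessions, and ILL7537 replicate 3, in Cy3, had 0.128 with the 4 Cy5 slides. A shared response, a dye effect and a batch shared by same-numbered slides cannot be told apart here. All 4 features called in ILL6002 at 24 h had the same sign in ILL7537 at 24 h (median 0.40; 68.2% of all features), where CA0011 NORMCON2 had 1.26 (adjusted p = 0.649).

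The ratio of many features differed with the dye orientation. In the limma model 244 of 759 had a dye term with an adjusted p under 0.05, 108 brighter in Cy5 and 136 in Cy3. Slides of a group with the same dye orientation correlated at a mean r of 0.411 over features (10 pairs), and slides with opposite orientation at -0.238 (20 pairs, 19 of them below 0).

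**Figure D2:**
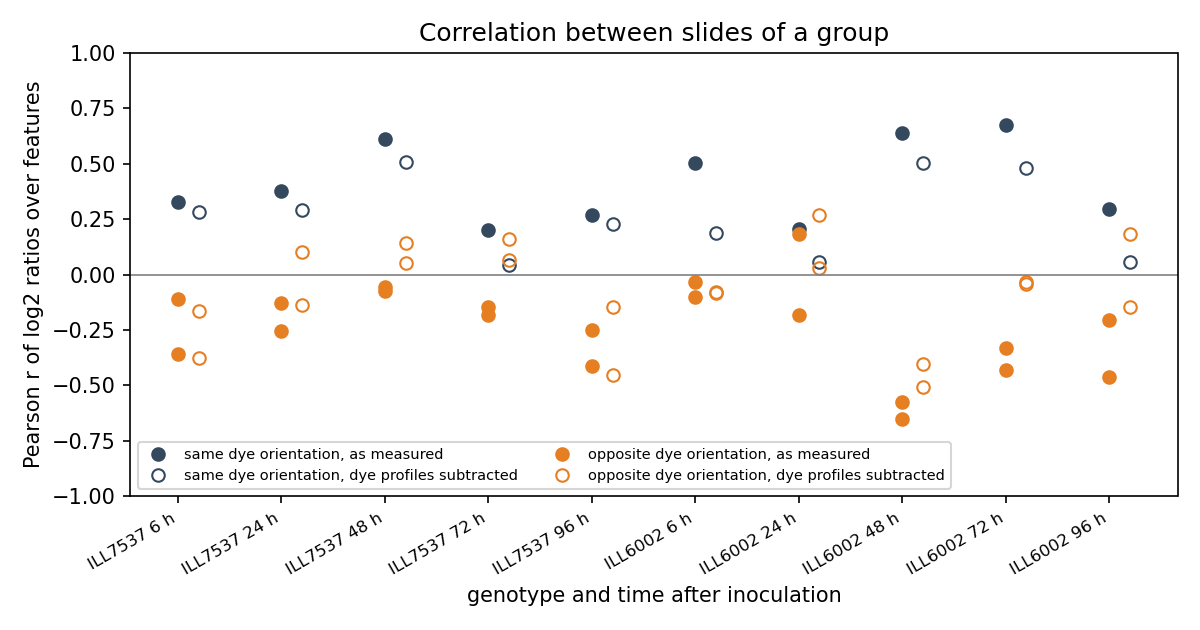
Pearson r over features (vertical axis) between the slides of each genotype and time (horizontal axis), as measured (filled) and after subtracting dye profiles of the other 4 times, estimated from separate slides for each slide of a pair (open). Blue pairs share the dye orientation and have means of 0.411 and 0.264; orange pairs have opposite orientation and means of -0.238 and -0.078.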

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

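The alternatives that left out the slide with 2 scan names or the 3 slides with 2 dye statements, blocked on time by replicate, or scaled the dye profile per slide were chosen after seeing the data. None of the 22 named feature and comparison pairs changed direction under an alternative that gave them a value. This is weak evidence, since they were picked from these data and the alternatives reuse most of the slides. Some, among them CA0640, had no value with the authors' spot filter. Calls were often lost. Over the alternatives the log2 ratio at ILL7537 48 h ranged from 0.92 to 2.48 for CA0011 NORMCON2 and from 0.25 to 2.09 for U459. The call was kept under 10 of 21 for each. U071 ranged from -1.79 to -0.63, with the call kept under 7 of 21. Dim channels limit U459, and CA0640 exceeded 2 times background in neither channel on the 3 ILL6002 24 h slides. The cause of the changes below was not established. Fewer slides or 3 slides alone leave less information, but some counts rose with a slide left out, to 64 at ILL7537 48 h and 122 at ILL6002 48 h. With the authors' background and spot filter, counts were 2 (ILL7537 48 h), 3 (ILL7537 mean), 8 (ILL6002 24 h), and 1 each for the genotype difference at 24 and 48 h. Only 1 of the 2, 1 of the 3 and 1 of the 8 were features called in the main model. With no background correction ILL7537 had 0 at 48 h and 5 for the mean, and with loess within grids 0 for the mean. Median centring gave 0 (ILL7537 48 h), 33 (ILL7537 mean), 0 (ILL6002 24 h), 2 (ILL6002 48 h) and 59 (ILL6002 mean). Equal slide spread gave 0 (ILL7537 48 h), 23 (ILL7537 mean), 1 (ILL6002 6 h), 2 (ILL6002 24 h), 2 (ILL6002 72 h) and 3 (genotype difference 72 h). With no spot left out ILL6002 24 h had 9, and with only features over 2 times background it had 12 and the ILL7537 mean 8. On their own slides ILL7537 48 h and ILL6002 24 h had 0. Array weights gave 0 (ILL7537 48 h), 2 (ILL7537 72 h), 59 (ILL7537 mean), 3 (ILL6002 6 h), 1 (ILL6002 48 h), 55 (ILL6002 72 h), 18 (ILL6002 mean), 23 (ILL6002 change with time) and 8 (genotype difference 72 h). The ILL7537 mean fell to 0 with the replicate block (consensus correlation 0.040), with time by replicate as block (0.127), with a 1.83-fold minimum, without the 3 slides with 2 dye statements, and with the dye profile scaled per slide. Same-numbered slides of the accessions correlated at -0.161 to 0.655, so the numbers were not taken as pairs. This range mixes pairs of same and opposite dye orientation. In 6 of 15 pairs r was highest with the own number, among them replicate 1 at 6 h (0.655), 24 h (0.301) and 48 h (0.41). At 48 h the mock channel of replicate 1 had a median background of 6996 in ILL7537 and 6283 in ILL6002. A batch shared by same-numbered slides was therefore not excluded. The authors' t-test was run on the ratios of this report, with adjusted p and the 1.83-fold minimum. On slide means it gave 0 for ILL7537 48 h and ILL6002 24 h. On grid values, which treat technical replicates as independent, it gave 5, 10, 76, 5 and 4 in ILL7537 at 6 to 96 h. In ILL6002 it gave 8, 31, 32 and 11 at 6 to 72 h. Before the minimum and the adjustment, 409 of 759 features had p under 0.05 in this t-test on grid values at ILL7537 48 h. Without the slide with 2 scan names ILL6002 24 h had 0. Without the 3 slides with 2 dye statements ILL7537 had 1 at 48 h and 1 at 72 h. With the dye profile scaled per slide ILL7537 48 h and ILL6002 24 h had 0. Leaving out 1 slide at a time gave ranges of 0 to 64 (ILL7537 48 h), 0 to 1 (ILL7537 72 h and 96 h), 0 to 51 (ILL7537 mean), 0 to 26 (ILL6002 24 h), 0 to 122 (ILL6002 48 h), 0 to 3 (ILL6002 72 h), 0 to 1 (ILL6002 mean), 0 to 23 (ILL6002 change with time), 0 to 1 (genotype difference 48 h) and 0 to 2 (genotype difference 72 h). A pair of slides left in a group is assumed to vary like the other groups. Coding slides as of unsettled dye and leaving them out was not run, since a dye was assigned to every slide and none was coded so; the 3 slides with differing statements were left out instead, as given above, and alternatives for gene lists were not run.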

Other observations

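All tests in this part other than the regroupings of slides and the comparison with the deposited ratios were chosen only after the results were seen; how the tests at ILL6002 24 h and 48 h and of opposite-dye slides were to be read was also settled after values of these tests were known, and the opposite-dye tests were recomputed with dye profiles that share no slide, after 2 earlier versions had given opposite readings.

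The other 2 features with a NORMCON tag were picked out after their values were seen, and their difference from CA0011 NORMCON2 was not tested. At ILL6002 24 h, where CA0011 NORMCON2 was called at 2.03, CA0020 NORMCON4 had 1.19 (adjusted p = 0.0696) and CA0018 NORMCON3 had 0.20 (adjusted p = 0.876), with 1.72, 0.95 and -1.62 on the 3 slides. At ILL7537 48 h, CA0020 NORMCON4 had 0.96 (adjusted p = 0.11) and CA0018 NORMCON3 had -0.28 (adjusted p = 0.763). CA0011 NORMCON2 was called in both ILL7537 48 h and ILL6002 24 h, the only one of the 24 features called in at least 1 group to be called in 2.

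Opposite-dye slides tended to oppose each other. Their mean r was -0.157 between groups (SE 0.0192 over 30 slides) and -0.238 within groups (SE 0.058 over 10 groups; -0.196, SE 0.045, without ILL6002 48 h), below the 0 or above that differences between plant samples alone would give, which argues against these as the whole cause of either. After subtraction of dye profiles from slides at times of neither slide, the mean between groups was 0.0061 (SE 0.0128). With the profile scaled per slide it was -0.0011 (SE 0.0133). Each differs from 0 by less than its SE, so a dye bias shared by all times may account for these pairs. It stays open, since slides of different groups with the same orientation still had a mean r of 0.0886 (0.114 scaled). No SE was computed for the latter. Within a group the mean after subtraction was -0.078 (SE 0.0633 over 10 groups), -0.082 (SE 0.0501) scaled, and -0.037 (SE 0.0532) without ILL6002 48 h, each less than 2 SE below 0. The shared bias therefore stays open within groups.

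The 4 calls of ILL6002 24 h ended without replicate 2. On that slide quality marks differed between the channels at 28.4% of spots, against 0 on the other 29 slides, and spot deviations correlated between the channels at 0.114, against 0.375 to 0.940 on the others, so its channels may come from different images. Whether this made the calls stays open, since without the slide the ratio fell by more than its SE for 2 of the 4 features (U016 from 1.16 to 0.92, U119 from 0.95 to 0.63) and not for CA0011 NORMCON2 (2.03 to 1.81) or CA0640 (-0.91 to -0.95), while SEs grew (CA0011 NORMCON2 from 0.417 to 0.514). A loss of calls from having a slide fewer stays open too: all 4 were called without replicate 1, but only 2 without replicate 3. A response of ILL6002 at 24 h was not excluded.

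ILL6002 48 h had 0 calls, and 122 without replicate 2. An exchange of inoculated and mock on replicate 2 may account for this: after subtraction of dye profiles it correlated at a mean of -0.454 with replicates 1 and 3, which correlated at 0.505 with each other. Replicate 2 is also the only slide of its group with inoculated RNA in Cy3, so an exchange and a dye effect on that slide cannot be told apart. A dye bias particular to 48 h is not decided either, since its test rests on 1 other slide, ILL7537 48 h replicate 3, with a mean r of 0.128 with the 4 slides in Cy5. Single opposite-dye pairs of other groups also opposed each other after subtraction of dye profiles. ILL7537 96 h replicates 1 and 3 had -0.453, and ILL7537 6 h replicates 1 and 3 had -0.376. The other opposite-dye pair of each of these groups had -0.145 and -0.164. A difference between the plants of the replicates was not tested and stays open, and no slide was turned or left out in the report's counts.

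Regrouping the slides gave the following; where the real count of calls is 0, every regrouping reaches it by construction, which tests nothing. With 3 slides in a group there are only 4 patterns of turning the sign of slides, too few for a share under 0.05; ILL7537 48 h had 21 calls and at most 0 in the other patterns (1 of 4 patterns reached the real count), ILL6002 24 h had 4 and at most 4 (2 of 4), and ILL6002 48 h had 0 and at most 152 (4 of 4), the last with replicate 2 turned, which restates that this slide runs against the other 2 and is no further evidence. For ILL7537 at 6, 24, 72 and 96 h and ILL6002 at 6, 72 and 96 h, 0 features were called in the real pattern and at most 0 in the others, so 4 of 4 reached it. For the ILL7537 mean, 2 of 100 sign patterns reached the 1 call (highest other 2). Only 1 of 100, the real one, reached the 162 features at an unadjusted p under 0.05 (highest other 149). That count as a whole thus stood above the other patterns drawn, in the model with no block, which says nothing on any single feature in it. Chance is not excluded, since 1 of 100 is the smallest share possible here and was not adjusted for the other counts examined. Regroupings were not run with replicate as block. The 1 call, CA0705, is lost with either replicate block, and another pattern called more, so no statement on chance is made for it. For the ILL6002 mean, 100 of 100 reached 0 calls (highest other 16); 9 of 100 reached the 87 features (highest other 150), so chance cannot be excluded for that count. For change with time, 100 of 100 assignments reached 0 calls in each genotype (highest other 1 in ILL7537 and 6 in ILL6002); 85 of 100 reached the 16 features of ILL7537 (highest other 89) and 20 of 100 the 69 of ILL6002 (highest other 138), so chance cannot be excluded for these 2 counts of features. For the genotype difference at 1 time there are 10 splits, too few for a share under 0.05; 0 calls were reached by 10 of 10 at each time, with highest others of 0, 2, 14, 0 and 0 at 6 to 96 h. For the mean difference, 100 of 100 exchanges reached 0 calls (highest other 1); 56 of 100 reached the 30 features (highest other 153), so chance cannot be excluded for that count.

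The deposited log2 ratios followed the recomputed background-subtracted ratios at r over features of 0.972, 0.951, 0.238, 0.958 and 0.950 in ILL7537 and 0.977, 0.742, 0.887, 0.863 and 0.968 in ILL6002 at 6 to 96 h. CA0011 NORMCON2 had deposited values of 0.83 at ILL7537 24 h and 0.53 at 72 h, which the deposited tables of these groups, not otherwise used here, list 10 times smaller; without this feature r was 0.950 and 0.958. With the fitted ratios of the report r was lower, from 0.198 (ILL7537 48 h) to 0.766 (ILL7537 72 h). In the deposited ILL7537 48 h column, 44 features exceeded 1.83-fold, 6 higher and 38 lower, whereas 17 of the 21 called here were higher. The 44 were taken by fold alone and the 21 by adjusted p, so the splits are not like for like. Among calls, 15 of 19 were higher with a 1.83-fold minimum, and 1 of 2 with the authors' background and spot filter. Of the 20 called features with a deposited value there, 16 had the same sign and 1 also exceeded 1.83-fold. At ILL7537 48 h 518 features had a deposited value, and 425 of these also had a recomputed background-subtracted ratio. At ILL6002 24 h the numbers were 374 and 347, and at ILL6002 72 h 551 and 549. In every other group the numbers were equal. ILL7537 48 h and ILL6002 24 h, the groups with calls, also had the lowest r. Whether their channel files are those behind the deposited values is not known. No reason for the low r of ILL7537 48 h was established.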
